A study of Rattus norvegicus with 6 samples.

How the data were processed

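Small RNA was sequenced from PC12 cells, a rat adrenal pheochromocytoma line. Per the labels, 3 libraries belong to a group called EC and 3 to a group called EN, and the labels do not spell out either abbreviation. RNA was extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq kit, per the labels' protocols. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

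The authors deposited a table of whole-number read counts for each mature miRNA in each library, and beside each count a value scaled to the library total (RPM). The submitters' processing notes list HISAT2 2.0.5 and the rat build Rnor 6.0. The step HISAT2 served, the counting program, the miRNA annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The table has 1289 rows, of which 584 carry the name of a known rat miRNA arm and 705 are predicted miRNAs that the authors numbered themselves. The predicted rows come with no sequence or position, so they are called newly named rows and described as a group. Each deposited RPM value equals the count divided by 1 library total within a rounding tolerance of 0.0015 in 100 percent of rows. That total lies between 17861218 and 21207786 reads, which exceeds the sum of the miRNA counts, and what reads it holds is not given in the sources used here.

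Counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr, libraries were scaled by TMM factors, and EN was compared with EC by the quasi-likelihood test with robust dispersion. P-values were adjusted by the Benjamini-Hochberg method over the 628 rows tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes are the absolute fold change divided by the square root of the F statistic. Levels are counts scaled to the library's miRNA counts (CPM) after TMM scaling, as mean ± SD over 3 libraries. No replicate block was used, and the pairing check is given with the alternatives.

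There were 14 lists of miRNAs fixed before the data were examined: nervous system, nerve injury and Schwann cell, endothelial, let-7 and miR-98, miR-17-92 and its paralogs, neuroendocrine and chromaffin, Dlk1-Dio3 cluster, muscle, blood cell, liver, miR-34 and p53 responsive, hypoxia, the miR-29 and miR-30 families, and 1 list that is not reported here. Lists with 3 or more tested members were compared by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 11 lists. Arm use was tested by limma on log2((5p + 1)/(3p + 1)) in pairs with a mean of 20 or more counts in both arms. Shares of counts were compared by two-sided exact permutation tests, for which 3 against 3 libraries give a smallest p of 0.1.

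The miRNAs named were set by a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls past the threshold with no overlap of the groups, the 10 miRNAs of highest mean level, and up to 4 members of each list, those past the threshold first and then the most abundant. Members that passed only when adjusted over the list alone, miRNAs with changed arm use, and rows of overlapping genes were named after their values were seen. Some members that the rule takes appear only among the alternatives.

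A RefSeq gene table of the GRCr8 assembly was used for names and neighbours. Its assembly differs from Rnor 6.0, so none of its coordinates are given. It matched 578 of the 584 known rows and holds 44 pairs of miRNA genes that overlap by at least 50 percent of the shorter gene. These pairs cover 96 rows, and reads of such rows cannot be assigned to 1 gene without a stated strand rule.

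Alternatives fixed before the data were examined were RLE factors, no scaling factors, no filter, a minimum mean of 10 CPM, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, no newly named rows, and no rows of the 5 most abundant miRNAs. Library totals implied by RPM and sums of overlapping rows, by locus and for each call of an overlapping gene, were added after seeing the data. The tests were run on simulated data first. With no change simulated, edgeR made 0 calls in 600 rows. With 587 simulated rows tested for the comparison of EN with EC, it recovered 25.6 percent of 2-fold changes and 83.2 percent of 4-fold changes, with 4 false calls among 106. Among changed rows of 100 CPM or more, 14.3 percent of 2-fold and 72 percent of 4-fold changes were called. The simulated spread came from dispersions fitted to these data, with a common coefficient of variation of 0.476. In the data, rows with a mean of 100 or more counts had a median SD within groups of 0.21 on the log2 scale. Calls there reached down to an absolute log2 fold change of 0.48. The simulated shares therefore need not hold for rows that vary less. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and figures.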

Results

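Mature miRNAs were counted in 6 libraries of PC12 cells, 3 labelled EC and 3 labelled EN, in a series whose title concerns Netrin-1, endothelial cell exosomes and peripheral nerve repair. Netrin-1 is a secreted guidance protein for growing axons. The comparison of EN with EC asks which miRNAs of these neuron-like cells differ between both groups. The EC libraries held 6433167, 6153582 and 6554639 miRNA counts, and the EN libraries held 5371351, 4521694 and 4553436. Log2 CPM values correlated across rows with r between 0.943 and 0.962 for libraries of the same group and between 0.941 and 0.957 for libraries of different groups, where rows are not independent replicates.

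Among known miRNAs higher in EN, miR-222-3p, which shares a primary transcript with miR-221, rose from 55273 ± 1797 to 77347 ± 3539 CPM (SD, n = 3). MiR-23a-3p, of the cluster with miR-27a and miR-24-2, rose from 30546 ± 2249 to 42958 ± 2386 CPM. The brain-enriched miR-128-3p rose from 719 ± 30.8 to 1162 ± 38.9 CPM, and miR-139-5p from 33.2 ± 3.24 to 65.4 ± 4.57 CPM. The largest rise of a known miRNA past the threshold was that of miR-451-5p, typical of red blood cell precursors. It stood at a low level of 8.10 ± 2.60 CPM in EC and 23.3 ± 6.26 CPM in EN. MiR-219b rose by 1.04 (SE 0.22) and miR-598-3p by 0.67 (SE 0.14) on the log2 scale.

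Among known miRNAs lower in EN, let-7i-3p fell from 365 ± 69.7 to 74.0 ± 32.2 CPM (SD, n = 3), a log2 fold change of -2.30 (SE 0.33). MiR-24-2-5p fell from 1883 ± 331 to 1026 ± 35.6 CPM, miR-28-5p from 1576 ± 32.6 to 1043 ± 42.7 CPM, and miR-374-5p from 1793 ± 82.5 to 1066 ± 158 CPM. MiR-32-5p changed by -0.98 (SE 0.16), miR-190a-5p by -1.05 (SE 0.22) and miR-188-5p by -1.02 (SE 0.21) on the log2 scale. MiR-106b-5p, a member of a paralog of the miR-17-92 cluster, changed by -0.85 (SE 0.14), as did miR-338-3p (SE 0.17). MiR-126a-5p, the less abundant arm of an endothelial miRNA, fell from 60.3 ± 5.20 to 33.2 ± 5.55 CPM. MiR-879-5p fell from 6.01 ± 2.16 to 0.618 ± 0.145 CPM, a low level in both groups. MiR-219b, miR-338-3p and miR-126a-5p belong to annotated genes that overlap another miRNA gene. With the rows of the overlapping gene added, a test chosen after seeing the data, miR-219b had a log2 fold change of 0.86 and no longer passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0610), while miR-338-3p at -0.83 (adjusted p = 0.0474) and miR-126a-5p at -0.87 (adjusted p = 0.0472) passed.

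By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 25 of 628 rows passed the threshold, 13 higher and 12 lower in EN, with adjusted p from 0.00167 to 0.0489. Of these rows, 7 were newly named, 6 of them higher with log2 fold changes from 1.07 to 4.84 and 1 lower at -1.64. The largest of these rises rest on few EC counts. These were 3, 5 and 9 for the row at 4.84, 4, 0 and 3 for that at 4.41, and 14, 9 and 18 for that at 3.17. The 3 EN values lay all above or all below the 3 EC values in 186 rows, or 29.6 percent, where chance gives 10 percent. With library totals implied by RPM in place of miRNA counts the calls were 101, with 13 higher and 88 lower, as the median of all rows moved from 0.02 to -0.30. There miR-222-3p, miR-23a-3p, miR-128-3p, miR-598-3p and miR-219b no longer passed. Leaving out 1 library gave 10 calls without EC replicate 1, 39 without EC replicate 2, 8 without EC replicate 3, 34 without EN replicate 1, 3 without EN replicate 2 and 2 without EN replicate 3. None of the known miRNAs passed in all 6 of these fits, and miR-451-5p passed in 0.

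**Figure D1:**
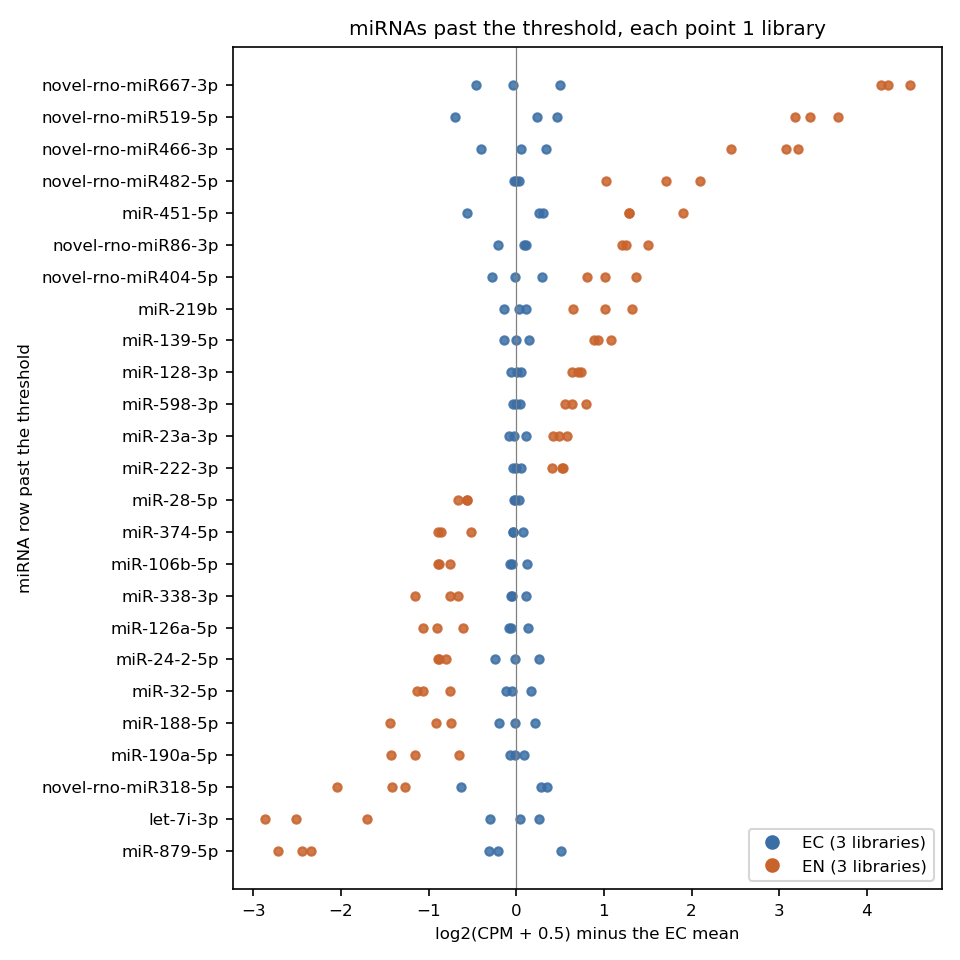
Log2(CPM + 0.5) of each library minus the EC mean (horizontal axis) for the 25 rows past the threshold (vertical axis). Each point is 1 library, and in each row the 3 EN points lie apart from the 3 EC points, with 13 rows to the right and 12 to the left.

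The 10 most abundant miRNAs were miR-22-3p, miR-222-3p, let-7c-5p, miR-24-3p, miR-21-5p, let-7b-5p, miR-191a-5p, miR-23a-3p, miR-99b-5p and miR-204-5p. Of these, miR-222-3p and miR-23a-3p passed the threshold. MiR-22-3p, the most abundant, stood at 74922 ± 2485 CPM in EC and 87733 ± 4152 CPM in EN (SD, n = 3). MiR-99b-5p stood at 28280 ± 3579 and 39103 ± 4730 CPM, miR-24-3p at 50900 ± 16077 and 37312 ± 374.6 CPM, and miR-21-5p at 44650 ± 4919 and 47365 ± 2416 CPM. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0937 for miR-22-3p, 0.0861 for miR-99b-5p, 0.310 for miR-24-3p and 0.665 for miR-21-5p. The 10 most abundant together took 45.2 ± 1.27 percent of counts in EC and 48.8 ± 0.89 percent in EN, a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.

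The miR-29 family, known for targeting collagen mRNAs, and the miR-30 family had negative log2 fold changes in 15 of 17 tested members, with a median of -0.39. MiR-29b-3p stood at 5660 ± 1635 CPM in EC and 2812 ± 446 CPM in EN (SD, n = 3), miR-29a-3p at 16927 ± 2035 and 13153 ± 1480 CPM, miR-30b-5p at 2168 ± 195.02 and 1611 ± 106.1 CPM, and miR-30d-5p at 2422 ± 913 and 1760 ± 207 CPM. None of the 17 passed edgeR's test over all rows, and 5 lower members passed when adjusted over the list alone. Over all rows 9 were lower with library totals implied by RPM, with a median of -0.73, 2 with total counts and 1 with RLE factors. The 5 were miR-29b-3p, miR-29c-3p, miR-30b-5p, miR-30c-5p and miR-30e-5p, with log2 fold changes of -1.01, -0.65, -0.43, -1.07 and -1.09. This was the 1 list of 11 to pass camera after Benjamini-Hochberg adjustment, with adjusted p = 0.00251. That call was lost with adjusted p = 0.420 with an estimated correlation. Of its members, 6 are rows of overlapping genes, and without such rows the adjusted p was 0.00582.

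**Figure D2:**
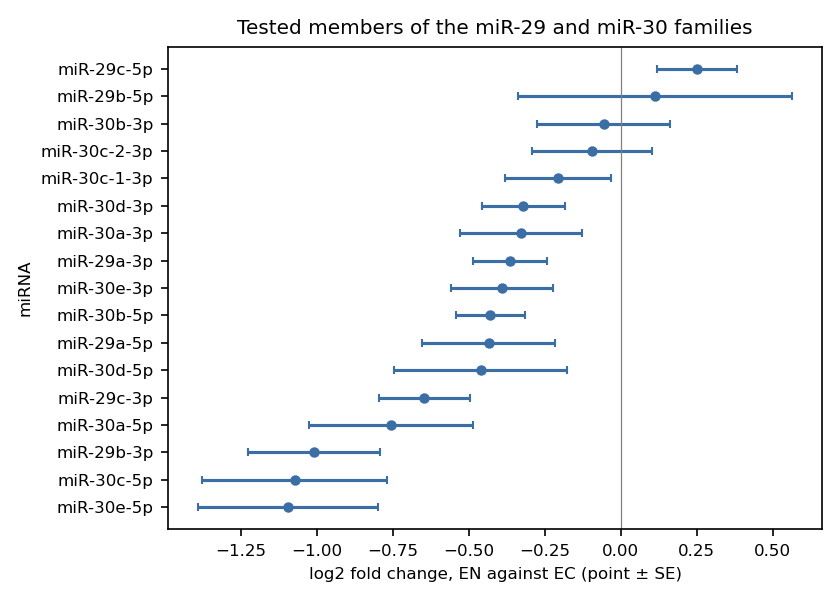
Log2 fold change of EN against EC (horizontal axis, points with SE bars) for the 17 tested miRNAs of the miR-29 and miR-30 families (vertical axis). The points of 15 miRNAs lie below 0, and the other 2 lie above it, though 0 of the 17 did with library totals implied by RPM.

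Of 24 tested nervous system miRNAs, 2 rose, miR-128-3p and miR-219b, and 22 did not pass. Adjusted over the list alone, 3 were higher and 1 lower, the added ones being miR-212-3p at 1.15 (SE 0.30) and miR-212-5p at -1.25 (SE 0.32). MiR-204-5p stood at 28338 ± 8667 CPM in EC and 32477 ± 2733 CPM in EN (SD, n = 3), and miR-218a-5p at 9395 ± 825 and 10753 ± 1625 CPM, without passing. The camera adjusted p of the list was 0.559, and its median of 0.18 became -0.14 with library totals implied by RPM. Of 31 tested nerve injury and Schwann cell miRNAs, 1 rose, miR-222-3p, and miR-29b-3p was lower when adjusted over the list alone. The camera adjusted p of that list was 0.139, or 0.646 without rows of overlapping genes. With library totals implied by RPM, 0 nervous system miRNAs were higher and 4 lower, and 0 nerve injury miRNAs were higher and 10 of 32 lower. Members are shared between the nerve injury list and the miR-29 and miR-30 list.

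Of 30 tested endothelial miRNAs, miR-222-3p and miR-23a-3p rose and miR-24-2-5p and miR-126a-5p fell, with a camera adjusted p of 0.559. With library totals implied by RPM, 0 were higher and 9 lower, and the median moved from -0.05 to -0.39. Adjusted over the list alone, 5 were higher and 6 lower. The higher ones outside the 4 above were miR-99b-5p, miR-99b-3p and miR-221-3p, with log2 fold changes of 0.47, 0.40 and 0.51. The lower ones were miR-24-1-5p, miR-151-5p, miR-130a-3p and miR-125b-1-3p, at -0.60, -0.33, -0.995 and -0.51. Of 20 tested let-7 and miR-98 members, let-7i-3p fell and 19 did not pass, also when adjusted over the list alone. The camera adjusted p was 0.139, or 0.261 without rows of overlapping genes. Let-7c-5p stood at 53513 ± 4102 CPM in EC and 50391 ± 4461 CPM in EN (SD, n = 3), let-7b-5p at 43655 ± 3600 and 40036 ± 7898 CPM, and let-7i-5p at 28861 ± 1115 and 26029 ± 698 CPM. Of 20 members of miR-17-92 and its paralogs, miR-106b-5p fell and miR-17-5p, at -0.58 (SE 0.14), was lower when adjusted over the list alone. The camera adjusted p of this list was 0.559, and miR-25-3p, of the same cluster as miR-106b, had a log2 fold change of 0.42 (SE 0.13) that did not pass. With library totals implied by RPM, 5 let-7 and miR-98 members and 5 of the miR-17-92 list were lower and 0 higher in both.

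Among markers of other cell types, miR-451-5p was the 1 of 4 tested blood cell miRNAs to rise, also adjusted over the list alone, with a camera adjusted p of 0.559. With library totals implied by RPM, 1 was higher and 1 lower, miR-155-5p at -0.55, and the median moved from 0.21 to -0.11. MiR-155-5p stood at 1145 ± 196 CPM in EC and 976 ± 16.4 CPM in EN (SD, n = 3), and miR-150-5p at 99.2 ± 18.1 and 141.2 ± 16.9 CPM. The liver miR-122-5p, at 7.96 ± 1.90 and 12.1 ± 3.36 CPM, and the muscle miR-499-5p, at 180.7 ± 12.6 and 164 ± 22.8 CPM, did not pass. None of 15 neuroendocrine and chromaffin miRNAs passed edgeR's test, over all rows or adjusted over the list alone, and miR-7a-5p stood at 1055 ± 80.2 and 1343 ± 131 CPM. The camera adjusted p of that list was 0.559. None of 9 miRNAs of the miR-34 and p53 list passed over all rows, with miR-34b-5p at -0.76 (SE 0.18) lower when adjusted over the list alone. Its camera adjusted p was 0.559, with a median of 0.04 and a mean of -0.06. With library totals implied by RPM the median was -0.29, with 0 higher and 2 lower, miR-34b-5p and miR-34c-5p. Of the Dlk1-Dio3 cluster, 3 of 49 rows were tested, none passed over all rows or adjusted over the list alone, and the camera adjusted p was 0.559. No known row matched the hypoxia list, so it could not be tested.

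Arm use changed in 6 of 107 miRNAs with both arms counted, by limma's test with Benjamini-Hochberg adjustment. The log2 ratio of 5p to 3p of miR-212, which neuronal activity induces, fell from 1.04 in EC to -1.24 in EN, a difference of -2.28 (SE 0.23, adjusted p = 0.00444). That of let-7i rose from 6.32 to 8.54, with adjusted p = 0.0176, and that of miR-28 fell from 4.22 to 2.90, with adjusted p = 0.0176. MiR-34b changed by -0.89 and miR-29c, whose annotated gene overlaps another miRNA gene, by 0.90. A newly named miRNA changed by -2.98, with 3p counts of only 3, 5 and 9 in the EC libraries. The count was 1 without EC replicate 1, EC replicate 3 or EN replicate 3, 2 without EN replicate 1 or 2, and 14 without EC replicate 2.

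MiRNA counts made up 31.9 ± 0.90 percent of the implied library total in EC and 25.8 ± 0.97 percent in EN (SD, n = 3), a two-sided exact permutation p of 0.1, the smallest possible. The implied totals themselves were 20008600 ± 1082830 and 18648600 ± 1170480 reads, with a two-sided exact permutation p of 0.3 for 3 libraries in each group.

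**Figure D3:**
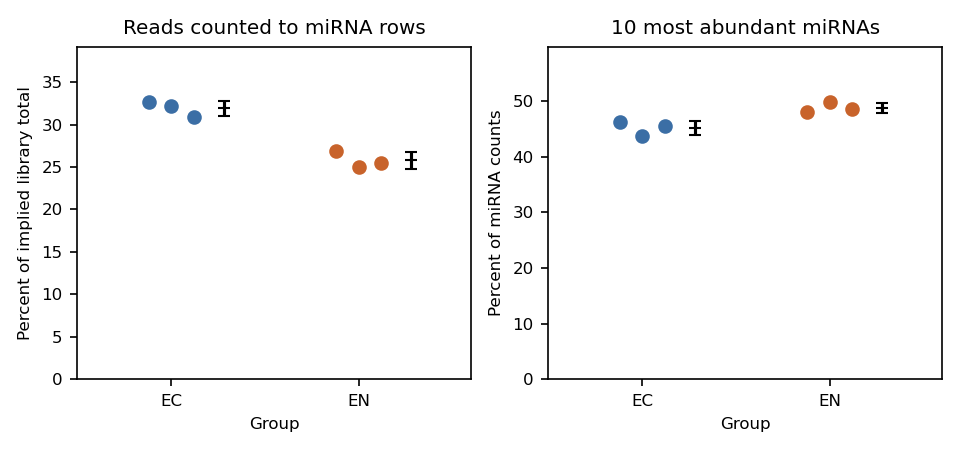
Percent of the implied library total counted to miRNA rows (left vertical axis) and percent of miRNA counts taken by the 10 most abundant miRNAs (right vertical axis) for each library by group, with mean and SD beside the points. The EN libraries lie between 24.99 and 26.9 percent on the left, and the EC libraries between 30.9 and 32.6 percent.

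Some abundant miRNAs could not be compared as deposited, because their rows were near 0 in some libraries and full in others of the same group. Let-7a-5p stood at 14588, 20735 and 20417 CPM in the EC libraries and at 26.3, 17303 and 137.1 CPM in the EN libraries. MiR-3596a, whose annotated gene overlaps a let-7a gene, stood at 10.7, 18.4 and 162.03 CPM in EC and at 18443, 34.1 and 14957 CPM in EN. MiR-125b-5p and miR-3588, miR-378a-5p and miR-3557-3p, miR-181a-1-3p and miR-3570, and miR-501-3p and miR-3560 were further such pairs. Summed, let-7a and miR-3596a had a log2 fold change of -0.18 (SE 0.16) and miR-125b and miR-3588 one of -0.33 (SE 0.19). The adjusted p was 0.580 and 0.336 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

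**Figure D4:**
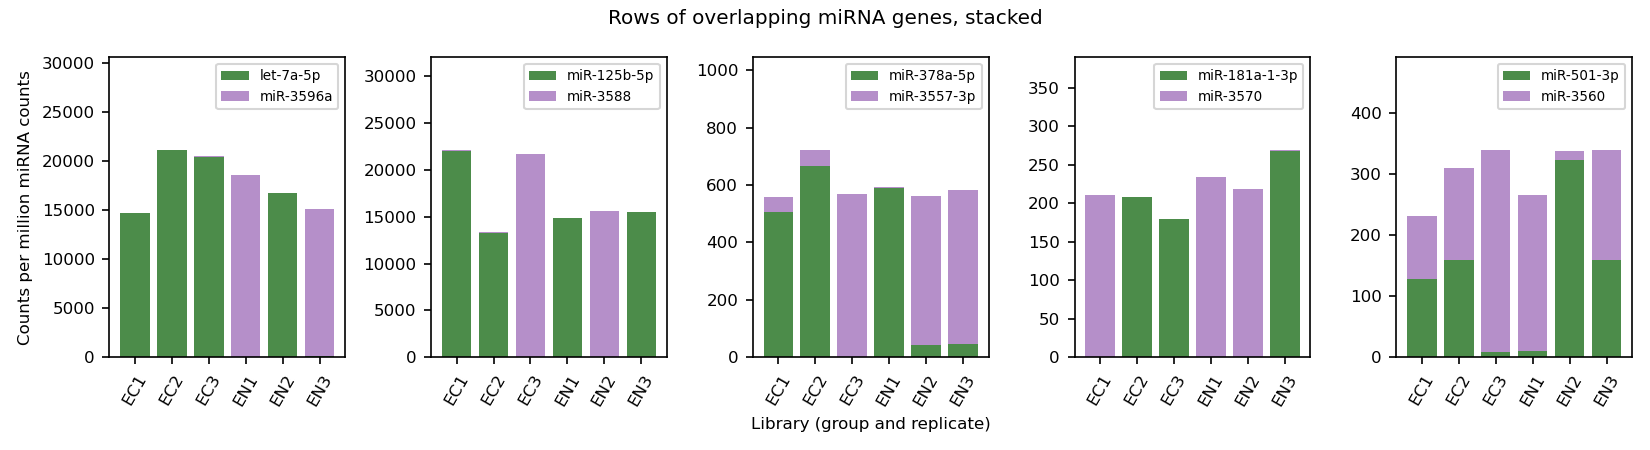
CPM (vertical axes) in each library (horizontal axes) for 5 pairs of rows whose annotated genes overlap, stacked. The color that fills the bar switches between libraries of the same group, while the height of the let-7a-5p and miR-3596a bar changes little beside that switch.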

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

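The 25 calls, 13 higher and 12 lower in EN, stayed within 1.5 times under RLE factors, total counts, limma-voom, a mean of 10 CPM, without newly named rows or the 5 most abundant miRNAs, and with overlapping genes summed, and none of the 25 changed sign in any alternative that tested its row. Without a filter there were 44 calls (21 higher, 23 lower), and DESeq2 gave 88 (39 higher, 49 lower), with no adjusted p in 152 rows. Library totals implied by RPM, a test chosen after seeing the data, gave 101 (13 higher, 88 lower), where the divisor is a total that exceeds the summed miRNA counts. Leaving out 1 library gave 2 to 39 calls, 2 to 23 higher and 0 to 26 lower. Of the 25 calls, 2 passed in all 6 such fits, both newly named rows with at most 18 counts in any EC library. Beyond the changed divisor, the cause of these shifts was not tested. Arm use calls ranged from 1 to 14 without 1 library. Lists past the threshold numbered 0 with an estimated correlation and 3 with fry, which tests a list without comparing it with other miRNAs. Fry added nervous system miRNAs (up) and nerve injury miRNAs (down). By camera without rows of overlapping genes, both of these lists had an adjusted p of 0.646. The gap in the share of the 10 most abundant miRNAs was 2.95 to 4.20 percentage points without 1 library.

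With the replicate number as a replicate block the calls were 2, 1 higher and 1 lower. Deviations of same-numbered libraries correlated at 0.091, -0.036 and 0.018, and those of different-numbered libraries at -0.124 to 0.095. EC replicate 2 and EC replicate 3 did not correlate best with their own number. These values cannot exclude a batch shared by number, since rows near 0 in some libraries and full in others entered them.

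Among miRNAs, reversals met only those that did not pass. The reversals with library totals implied by RPM came with the changed divisor, which moved the median of all rows from 0.02 to -0.30. The cause of the others was not tested. Among the lists reported here, endothelial miRNAs turned from down to up by camera without rows of overlapping genes. The list passed neither way, with camera adjusted p of 0.559 and 0.646. With totals implied by RPM the log2 fold changes became -0.19 (miR-181a-5p), -0.27 (miR-192-5p), -0.13 (miR-204-5p), -0.24 (miR-21-5p), -0.14 (miR-218a-5p), -0.10 (miR-22-3p), -0.30 (miR-34a-5p), -0.19 (miR-34b-3p), -0.0097 (miR-429), -0.22 (miR-92a-3p) and -0.24 (miR-93-5p). MiR-155-3p became 0.022 under limma-voom. Without newly named rows, miR-191a-5p became 0.059, miR-27a-3p 0.020 and miR-497-5p 0.024. MiR-34a-5p became -0.00093 without a filter and -0.0143 with overlapping genes summed. Without 1 library, let-7b-5p ranged from -0.25 to 0.0043, miR-155-3p from -0.37 to 0.29, miR-191a-5p from -0.091 to 0.034, miR-192-5p from -0.042 to 0.30, miR-204-5p from -0.013 to 0.37, miR-27a-3p from -0.12 to 0.030, miR-34a-5p from -0.0141 to 0.10, miR-376a-3p from -0.67 to 0.10, and miR-497-5p from -0.098 to 0.014.

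Other values kept their direction among miRNAs of the naming rule and those past the threshold over a list alone, for which alternatives were computed. Over all alternatives, calls passed in 288 fits, or 69.7 percent, and other named miRNAs newly passed in 53. Alternatives for tables of normalized values alone were not run, since the table holds counts. Depth limits rows such as miR-879-5p, at under 1 CPM in EN.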

Other observations

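The tests of reads shared between rows, of a failed library and of partner rows were chosen after the result was seen. Of 23 clusters of neighbouring genes tested by camera, 5 had all rows negative, 3 had all rows positive and 15 had rows of both signs. In the clusters of lowest camera p, all 6 rows of the Mir188, Mir362, Mir500 and Mir532 genes had negative log2 fold changes, with a median of -0.47, and all 4 rows of Mir221 and Mir222 had positive ones, with a median of 0.39, though 2 of these 4 with library totals implied by RPM. After adjustment over clusters, camera gave 0.0679 and 0.192, and 0.652 for both with an estimated correlation. Over 77 genes in 29 clusters within 10 kb of each other in the RefSeq table of GRCr8, the mean difference within clusters was 0.46 against a median of 0.51 in 10000 random assignments, a one-sided permutation p of 0.143. Whether neighbouring genes may have changed together stays open.

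In 20 rows with a mean of 100 or more counts, libraries of the same group differed by 8-fold or more, while the median SD within groups over 325 such rows was 0.21 on the log2 scale. Of these, 10 form 5 pairs of overlapping annotated genes, and alone they had SDs from 1.66 to 5.20, while the sums of the pairs had SDs from 0.14 to at most 0.29 (0.293). Where a row had several such partners, the one most opposed to it within groups was taken, so the steady sums are partly selected. MiR-378a-3p, of a gene that overlaps that of miR-3557, is another of the 20 rows and was left out of these pairs. Its sum with miR-3557-3p had an SD of 2.81. Its sum with miR-3557-5p had an SD of 0.39, against 3.17 for miR-378a-3p and 0.20 for miR-3557-5p alone. A candidate explanation for the 5 pairs is that reads of 1 locus were assigned to either of 2 overlapping genes, library by library. A mislabelled or failed library is argued against by 19 different sets of low libraries. The adjusted p of 0.580 for the summed let-7a and miR-3596a rows bears on the level of that sum alone, since summing removes the switch, so whether the assignment differs between the groups stays open. Of the 10 other rows, miR-378a-3p among them, 6 had a sum with another such row of SD under 0.5, but each partner was the best of 9. Reordering libraries gave permutation p of 0.0278, 0.0556 and 0.111 for the 3 pairs. The lowest was that of let-7c-2-3p with let-7a-1-3p, and 36 orders allow no smaller p. Their sum had an SD of 0.19, against 4.81 and 4.20 alone. Sharing stays open for all 10, with this pair the strongest candidate.

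The lower share of miRNA counts in EN was not limited to the 10 most abundant miRNAs. The other rows took 17.5 ± 0.63 percent of the implied total in EC and 13.2 ± 0.71 percent in EN, a ratio of 0.754, which follows from the shares already given. Reads outside the miRNA rows made up 74.2 percent of the implied total in EN and 68.1 percent in EC, and a rise of another RNA class could account for that, but the table holds no such class. A difference between the groups in miRNA content stays open as well, untested.

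Let-7i-3p, miR-24-2-5p and miR-126a-5p are less abundant arms that fell. A fall of such arms as a class could underlie this, but over the minor arms of pairs without overlapping genes, which include let-7i-3p and not the other two, the median was -0.09 (SE 0.07) and the camera p 0.0808, or 0.146 with an estimated correlation. The major arms of the same pairs had a median of -0.07 (SE 0.07), and 1 minor and 5 major arms were lower past the threshold, so a fall of minor arms cannot be told apart from no shift.

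The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 25 miRNAs and the highest other 3, so 1 split reached the count. For arm use it gave 6 against 0, reached by 1 split. For lists it gave 1 against 1, reached by 3 splits.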
